A study of Homo sapiens with 4 samples.

How the data were processed

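RNA immunoprecipitation followed by sequencing (RIP-seq) was carried out on the human skin fibroblast line WS1 without irradiation (0 Gy) or with 5 Gy of X-rays, per the labels. HuR, encoded by ELAVL1, is an RNA-binding protein known to bind U-rich and AU-rich stretches of mRNA. At each dose there was 1 library of RNA recovered with HuR and 1 library of RNA recovered with control immunoglobulin (IgG), which makes 4 libraries with 1 per group. There were no replicates, so no p-value between the doses was computed, and a difference between the lists has no replicate check. Expression libraries from the same study were not used here.

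The values used were 2 peak lists, 1 per dose, each a HuR library called over the IgG library of its own dose. Reads were processed with cutadapt 1.9.1 and Bowtie2 2.2.4 on the genome build hg19, per the submitters' processing notes. The peaks carry names that begin with MACS, a caller that models read pile-ups with a Poisson background. The names of both deposited lists carry the settings 1e-06, 10 and 30. The first has the form of a p-value cutoff, and the other two match the form of the fold range from which MACS builds its model, although the names do not say what they stand for. The MACS version and any other settings are not given in the sources used here. Each line of the lists as deposited gives a chromosome, a start, an end, a peak name and a score, with no strand and no gene. The score is the authors' peak score as deposited. The scores start at 60.00 in the 0 Gy list and 60.01 in the 5 Gy list, which is what −10 log10 of a p-value of 1e-06, the value in the list names, gives. Scores of 2481 peaks at 0 Gy and 2000 peaks at 5 Gy are tied at 3100, so the order among the strongest peaks is not resolved. Another 85 peaks at 0 Gy and 70 at 5 Gy score above 3100, up to 3233.06, which is also the score of the smallest positive number in double precision. Whether the tied peaks had smaller or larger p-values than those above 3100 is not stated in the sources, and the deposited order of the 2 kinds carries no meaning here. Values in the closing section argue against reading the tie as weaker than scores above 3100. The score was used to rank or filter peaks within its own list and within pairs of peaks. In some counts the same minimum score was applied to both lists, and in the closing section the 0 Gy scores were scaled. The score grows with sequencing depth, and the depth of the 4 libraries is unknown from these lists, so a common minimum score need not be equally strict in both. The lists give no read count per peak, so no interval from reads could be computed.

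The positions were taken to be hg19, per the submitters' processing notes. On chromosome 1, 4 peaks of the 0 Gy list and 2 of the 5 Gy list end beyond the last gene of the available GRCh38 gene table, so those coordinates could not be used with the lists. No hg19 genome or annotation was at hand. Peaks were therefore not joined to genes, and they are named by position, with the start counted from 1. The region classes of peaks, the sequence content of peaks, the genes with a peak and 19 prepared gene lists (352 entries, markers of other cell types among them) were not analysed here. Chromosome Y enters the totals and is not described separately.

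A peak was called shared when at least 1 bp overlapped a peak of the other list, with strand ignored because the lists hold none. Placement within the same gene and region class, which had been planned, was replaced by 2 other controls. Peaks were placed at random on their own chromosome, between the first and last peak of either list, in 100 placements. The whole list was also shifted by 20 kb in each direction, which keeps the local density of peaks. Overlap was computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the number of shared peaks was the same with bedtools 2.31.1. Shares have Wilson 95% intervals. The interval of a ratio of peak numbers comes from the Wilson interval of the 5 Gy share of both lists together, and that of a median from binomial order statistics. All these intervals treat peaks as independent and cover counting error only. They do not cover variation between cultures or immunoprecipitations. Pairs of 1 peak of each list lying only against each other were used to compare lengths and ranks of scores, with Spearman's rho across peaks, which are not replicates (interval from 200 resamples of the pairs). Peaks of both lists within 10 kb of each other were joined into regions. The counting of overlaps was checked on a simulated list made from the 47930 peaks at 0 Gy. Part of the peaks were copied with a small shift, and the rest were moved off the chromosomes. Of the copied peaks 100.00% were found shared. Of the moved peaks 1.31% were called shared, through the shifted copy of a neighbour. These values follow from the setting and give no rate of sharing by chance.

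Peaks to be named were the 10 highest-scoring of each list, a rule fixed before the data were examined together with the groups and part of the alternatives. Because of the tie at 3100, the 10 longest of the tied peaks were named as well. The peaks of one list only, the regions and the pairs with the largest change of rank were chosen after their values were seen. The alternatives were a stricter score, merging or joining of peaks, a 50% reciprocal overlap, equal list sizes, a 100 bp tolerance and counting of base pairs or regions.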

Results

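HuR-bound RNA was profiled by RIP-seq in WS1 skin fibroblasts at 0 Gy and 5 Gy, to compare the transcribed regions recovered with HuR over IgG at each dose. The 0 Gy list held 47930 peaks covering 37.85 Mb, and the 5 Gy list held 36216 peaks covering 34.71 Mb of hg19. Each list rests on 1 HuR library and 1 IgG library, and read depth is unknown. All differences below are between these lists and have no replicate check. The scores are the authors' peak scores from their deposited lists.

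The 5 Gy list held fewer and longer peaks than the 0 Gy list. The number of peaks at 5 Gy was 75.6% of that at 0 Gy (95% interval of counting error 74.5 to 76.6). The median peak length was 559 bp at 5 Gy (95% interval 554 to 563) and 448 bp at 0 Gy (95% interval 445 to 452). The median gap between neighbouring peaks of a list was 4151 bp at 5 Gy and 2717 bp at 0 Gy. After peaks within 10 kb of each other were joined in each list, the number at 5 Gy was 90.7% of that at 0 Gy. Among peaks with a score of at least 1000 there were 5866 at 0 Gy and 4730 at 5 Gy, which is 80.6% (95% interval 77.6 to 83.8).

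The lower peak number at 5 Gy was spread over the chromosomes. Across the 22 autosomes and X, the 5 Gy list held between 71.3% (chromosome 20, 925 against 1297 peaks) and 79.3% (chromosome 14, 1006 against 1269 peaks) of the number at 0 Gy. The 95% interval of each of the 23 chromosomes included the genome-wide 75.6%. Chromosome 1 carried the most peaks in both lists, with 4953 at 0 Gy and 3717 at 5 Gy, followed by chromosome 3 with 3639 and 2729. Covered length at 5 Gy ranged from 86.1% of that at 0 Gy on chromosome 21 to 97.0% on chromosome 8.

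**Figure D1:**
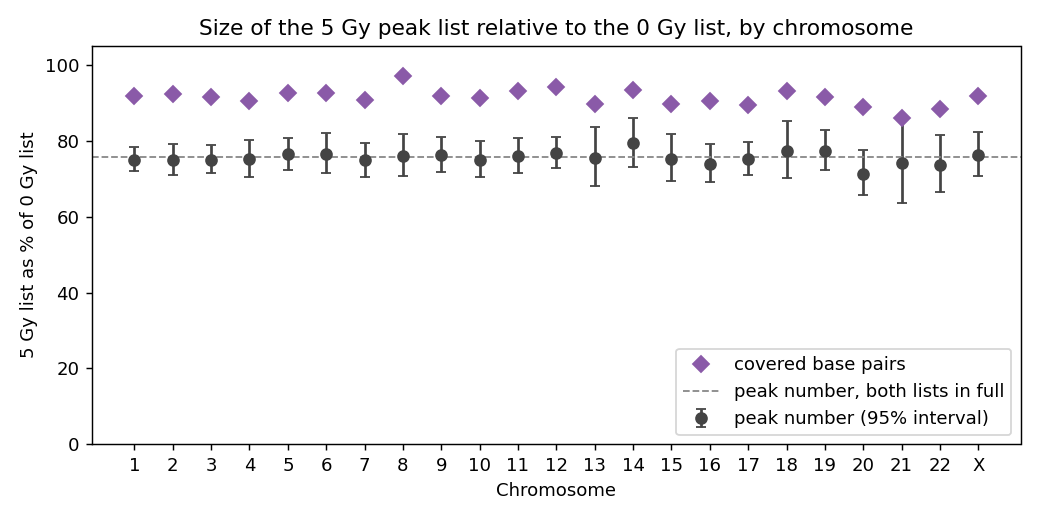
The vertical axis gives the 5 Gy list as a percentage of the 0 Gy list for each chromosome on the horizontal axis; circles are peak numbers with 95% intervals of counting error, diamonds are covered base pairs, and the dashed line is the genome-wide peak number. Every interval includes 75.6%, and the covered base pairs lie between 86.1% and 97.0%.

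Of the 0 Gy peaks, 27866 (58.1%, 95% interval 57.7 to 58.6) overlapped a 5 Gy peak, and of the 5 Gy peaks, 26431 (73.0%, 95% interval 72.5 to 73.4) overlapped a 0 Gy peak. Peaks placed at random on the same chromosome overlapped the other list in 2.14% of cases for 0 Gy peaks (range 1.99 to 2.30 over 100 placements) and 2.66% for 5 Gy peaks (range 2.40 to 2.89). Shifting a list by 20 kb, which keeps the local density of peaks but not their place within a gene, gave overlaps of 11.5% for the 0 Gy list and 14.2% for the 5 Gy list. With at least 50% of each peak required to overlap, the shares were 41.9% of 0 Gy peaks and 55.4% of 5 Gy peaks. The shared sequence came to 25.55 Mb, or 67.5% of the covered length at 0 Gy and 73.6% at 5 Gy. A 5 Gy peak lay against at least 2 peaks of the 0 Gy list in 3361 cases (9.28%), and a 0 Gy peak lay against at least 2 peaks of the 5 Gy list in 2297 cases (4.79%).

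The share of overlapping peaks was higher in higher score classes, whose peaks were also longer. Among peaks with a score from 60 to under 70, 26.0% of 0 Gy peaks (95% interval 24.9 to 27.1, 6348 peaks) and 40.2% of 5 Gy peaks (95% interval 38.8 to 41.6, 4536 peaks) were shared. From 250 to under 500, the shares were 85.7% and 94.7%. The median length ran from 336 bp in the lowest class to 2154 bp in the highest at 0 Gy, and from 391 to 2344 bp at 5 Gy. After a 20 kb shift, the overlap ran from 9.1% in the lowest class to 17.7% in the highest at 0 Gy, and from 11.2% to 19.6% at 5 Gy. At scores of at least 1000, 99.52% of 0 Gy peaks and 99.92% of 5 Gy peaks overlapped a peak of any score in the other list. This left 28 peaks of the 0 Gy list and 4 of the 5 Gy list without a match. Of the 20064 peaks found only at 0 Gy, 83.1% scored under 150, as did 88.1% of the 9785 found only at 5 Gy. In the lists in full, 22271 of 47930 peaks at 0 Gy and 17569 of 36216 at 5 Gy scored at least 150. The median score was 87.4 for peaks found only at 0 Gy and 259.5 for shared 0 Gy peaks. At 5 Gy the corresponding medians were 82.4 and 212.9.

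**Figure D2:**
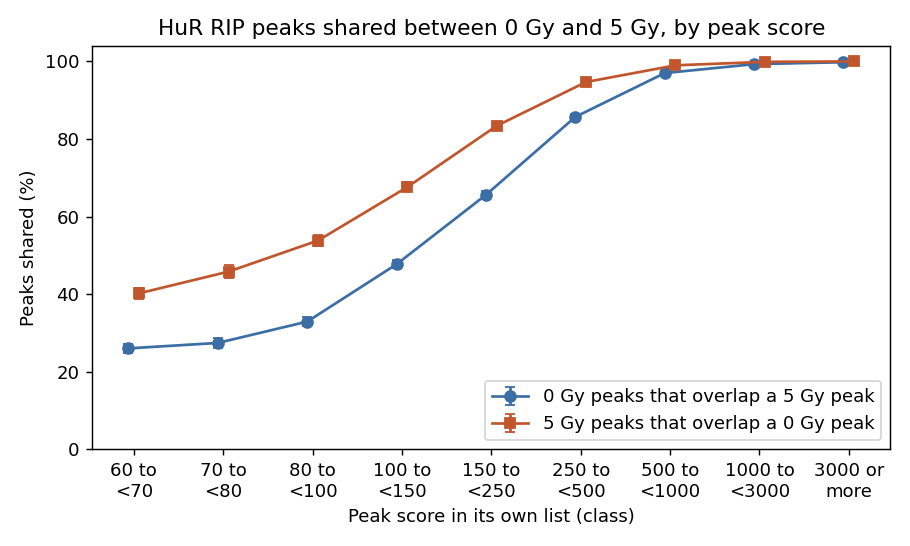
The vertical axis gives the percentage of peaks that overlap a peak of the other dose, and the horizontal axis the class of the peak's score in its own list; circles are 0 Gy peaks, squares are 5 Gy peaks, and bars are Wilson 95% intervals. The share runs from 26.0% of 0 Gy peaks and 40.2% of 5 Gy peaks in the lowest class to over 99% in both lists at scores of at least 1000.

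The 10 highest-scoring peaks of each list and the 10 longest of its peaks tied at 3100 all overlapped a peak of the other list. A score above 3100 is not taken to mark a stronger peak than the tie at 3100, and values in the closing section argue against that reading. The highest score at 0 Gy, 3233.06, was given to 2 peaks, on chromosome 10 (59951800 to 59956638, 4839 bp) and chromosome 15 (39885571 to 39886106, 536 bp). At 5 Gy, a score of 3233.06 was given to peaks on chromosome 16 (50138817 to 50140326, 1510 bp) and chromosome 18 (1362217 to 1363328, 1112 bp). The fourth-ranked 5 Gy peak, with a score of 3224.03, extended over 8656 bp of chromosome 11 (65266313 to 65274968). The 10 longest of the peaks tied at 3100 ranged from 10229 to 17257 bp at 0 Gy and from 10278 to 18027 bp at 5 Gy. The longest at both doses lay on chromosome 19, from 57801817 to 57819073 at 0 Gy and from 57801966 to 57819992 at 5 Gy. On chromosome 12, the 0 Gy peak from 54624733 to 54636304 (11572 bp) and the 5 Gy peak from 54624725 to 54635895 (11171 bp) nearly coincided, as did the peaks on chromosome 17 from 79836300 to 79846528 (10229 bp) and from 79836255 to 79846532 (10278 bp). On chromosome 8, 1 peak of 12887 bp at 5 Gy (128806023 to 128818909) lay over 8 separate 0 Gy peaks with a summed length of 12262 bp. On chromosome 5, 1 peak of 12843 bp at 0 Gy (14157669 to 14170511) overlapped 4 peaks at 5 Gy. Their summed length of 14353 bp exceeded that of the 0 Gy peak, so they reached beyond it.

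Of the 2627 peaks with a score of at least 3000 at 0 Gy, 6 had no match at 5 Gy. One of them was a 4847 bp peak on chromosome 17 (28791563 to 28796409) with a score of 3142.94, and the nearest 5 Gy peak was 9.4 kb away. The others were tied at 3100 and are not ranked against it. Peaks tied at 3100 without a match at 5 Gy lay on chromosome 5 (14369419 to 14378314, 8896 bp), chromosome 6 (36562108 to 36569300, 7193 bp, and 36569512 to 36572045, 2534 bp), chromosome 10 (71926778 to 71930331, 3554 bp) and chromosome 17 (75088999 to 75091107, 2109 bp). For the pair on chromosome 6, the nearest 5 Gy peak was 49.2 kb from the first and 56.6 kb from the second. For the peak on chromosome 10 it was 0.1 kb away. The next score, 1871.21, was that of a 2746 bp peak on chromosome 10 (71922345 to 71925090), with a 5 Gy peak 0.4 kb away. A further 0 Gy peak on chromosome 6 (26158336 to 26159109, 774 bp) had a score of 1775.22, and the nearest 5 Gy peak was 5.0 kb away.

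Of the 2129 peaks with a score of at least 3000 at 5 Gy, 1 had no match at 0 Gy, with a score tied at 3100. It covered 4126 bp of chromosome 20 (31442601 to 31446726), and the nearest 0 Gy peak was 11036 bp away. The next score was 1179.28, for a 1855 bp peak on chromosome 10 (95660480 to 95662334), with the nearest 0 Gy peak 6.4 kb away. A 1898 bp peak on chromosome X (68060074 to 68061971) scored 1035.81, with a 0 Gy peak 1.3 kb away. A 2040 bp peak on chromosome 4 (122615267 to 122617306) scored 1012.85, with a 0 Gy peak 1.1 kb away. The 3255 bp peak on chromosome 2 (14774062 to 14777316, score 850.92) was the most isolated of the 10 strongest unmatched 5 Gy peaks, with the nearest 0 Gy peak 897.4 kb away.

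When peaks of both lists within 10 kb were joined, they formed 15970 regions. Both doses contributed peaks to 10958 regions (68.6%), which held 90.4% of all 0 Gy peaks and 94.8% of all 5 Gy peaks. Regions chain neighbouring peaks, and the most covered spanned 137.5 kb, so a peak in such a region may lie far from any peak of the other list. No random placement or shift was computed for regions. Peaks of the 0 Gy list alone made up 3409 regions (21.3%), of which 2595 consisted of 1 peak and 250 of at least 3. Peaks of the 5 Gy list alone made up 1603 regions (10.04%), of which 1398 consisted of 1 peak and 49 of at least 3. By covered length, the 0 Gy regions without a 5 Gy peak were led by chromosome 6 from 36562108 to 36576026 (3 peaks, 10.1 kb covered), followed by chromosome 5 from 14369419 to 14378314 (1 peak, 8.9 kb) and chromosome 7 from 94285642 to 94299027 (2 peaks, 6.8 kb, highest score 489.47). The 5 Gy regions without a 0 Gy peak were led by chromosome 11 from 122940587 to 122954729 (2 peaks, 4.3 kb covered, highest score 526.58) and chromosome 20 from 1391355 to 1398211 (6 peaks, 4.2 kb, highest score 674.76).

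Among regions with peaks at both doses, the most covered by both lists together lay on chromosome 5 from 14143346 to 14280811. It had 55 peaks over 75.7 kb at 0 Gy and 38 peaks over 55.9 kb at 5 Gy. The next, on chromosome 1 from 94632211 to 94713347, had 41 peaks over 55.1 kb at 0 Gy and 38 peaks over 58.8 kb at 5 Gy. Coverage at 5 Gy was lower on chromosome 20 from 30946796 to 31035406 (46 peaks over 33.4 kb at 0 Gy, 21 peaks over 15.0 kb at 5 Gy) and on chromosome 18 from 57291946 to 57365403 (29 peaks over 21.4 kb against 10 peaks over 6.0 kb). It was also lower on chromosome 1 from 164528312 to 164623026 (38 peaks over 19.4 kb against 8 peaks over 4.8 kb). Coverage at 5 Gy was higher on chromosome 17 from 62538264 to 62659165 (51 peaks over 38.3 kb at 0 Gy, 49 peaks over 54.2 kb at 5 Gy) and on chromosome 2 from 29117486 to 29171303 (22 peaks over 13.3 kb against 22 peaks over 23.2 kb). On chromosome 12, the region from 69201881 to 69244632 had 15 peaks over 25.5 kb at 0 Gy and 11 peaks over 34.8 kb at 5 Gy, and the region from 109071402 to 109124446 had 10 peaks over 3.7 kb and 22 peaks over 12.6 kb.

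**Figure D3:**
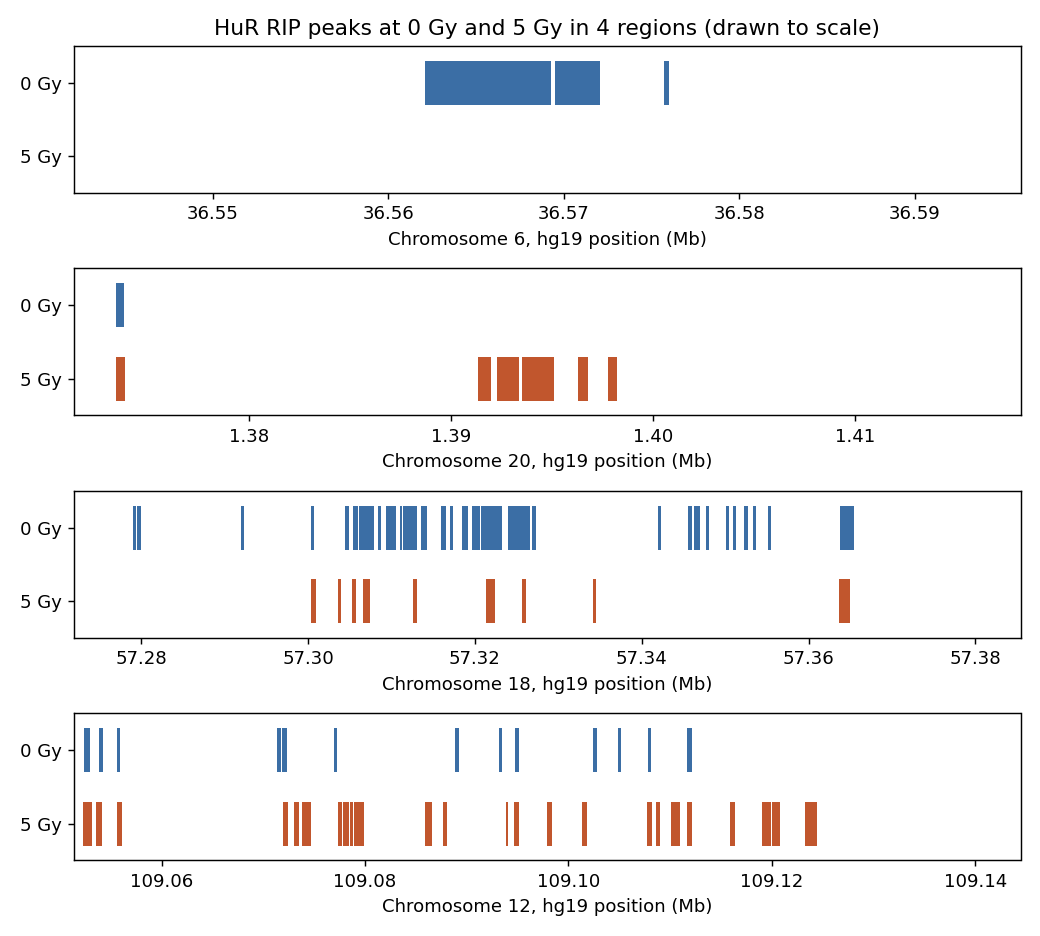
Each panel draws the peaks of the 0 Gy list (upper row) and the 5 Gy list (lower row) to scale along hg19 positions in Mb, for 1 region and its flanks of 20 kb, with narrow gaps between peaks not resolved at this scale. Chromosome 6 shows 3 peaks at 0 Gy alone, chromosome 20 a group of 6 peaks at 5 Gy alone, chromosome 18 fewer peaks at 5 Gy (10 against 29) and chromosome 12 more (22 against 10), counted in the regions without their flanks.

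In 19750 pairs, 1 peak of each list lay only against each other. Across these pairs the scores correlated with a Spearman rho of 0.78 (95% interval 0.78 to 0.79), and 1671 pairs had scores of at least 3100 at both doses. The percentile rank of a peak among the pairs differed between the doses by a median of 9.7 points in either direction. Both rho and these ranks used the scores as deposited, so that scores above 3100 ranked over the tie at 3100. Values in the closing section argue against that order. The 5 Gy peak was the longer in 58.3% of the pairs, and the median ratio of lengths was 1.03 (95% interval 1.03 to 1.03). Ranks were furthest below those at 0 Gy on chromosome 8 (52858991 to 52861594 at 0 Gy, score 1251.77 at 0 Gy and 61.64 at 5 Gy) and chromosome 17 (48261440 to 48263049 at 0 Gy, 1101.45 and 60.69). They were furthest above on chromosome 12 (76653700 to 76655738 at 5 Gy, 63.99 at 0 Gy and 1216.01 at 5 Gy) and chromosome 10 (126673196 to 126675811 at 5 Gy, 65.72 and 910.57). The third-largest gain in rank was that of a 5 Gy peak on chromosome 17 (4935787 to 4937673), which scored 85.83 at 0 Gy and 1324.01 at 5 Gy.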

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

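With 13 alternative settings applied to 6 results, 34 values were recomputed; 4 lay within the counting interval of the reported value and 30 outside, and none turned the order of the lists by peak number or by median length. The 5 Gy list as a percentage of the 0 Gy list (75.6%) was 81.4% with peaks within 1 kb joined, 90.7% with peaks within 10 kb joined, 78.0% at a score of at least 100 and 80.6% at a score of at least 1000. It stayed at 75.6% at scores of at least the list's median, which the setting fixes by construction, and after merging of overlapping peaks, of which the lists hold none. For the same reason, merging left the median lengths at 448 bp (0 Gy) and 559 bp (5 Gy). The 4 values within the interval were thus all fixed in advance. The median lengths at 0 Gy and 5 Gy were 708 and 909 bp at scores of at least the list's median, 599 and 740 bp at a score of at least 100, 1726 and 1976 bp at a score of at least 1000, and 548 and 586 bp in one-to-one pairs. The shared percentages of 0 Gy and 5 Gy peaks were 41.9% and 55.4% when at least 50% of each peak had to overlap (so that under this rule fewer 0 Gy peaks were shared than not), 68.3% and 67.0% with the same number of peaks from each list, 65.3% and 82.7% at scores of at least the list's median and 60.1% and 74.7% with peaks within 100 bp counted. They were 74.6% and 86.5% at a score of at least 100, 99.5% and 99.9% at a score of at least 1000, 67.5% and 73.6% in base pairs, and 90.4% and 94.8% by regions within 10 kb. Equal list sizes force nearly equal shares by construction. Spearman's rho across pairs was 0.82 with a 50% reciprocal overlap and 0.69 with both scores under 3000. The joining distances, score minima, base pair and region counts, one-to-one lengths and the rho under 3000 were chosen after seeing the data. The effect of ignoring the strand could not be measured, because the lists hold none. The alternatives on genes, region classes, sequence and gene lists were not run for want of an hg19 annotation. No paired analysis was possible because each group has 1 library. The unknown depth of the 4 libraries limits all comparisons of peak number.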

Other observations

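The test of peaks with a score of at least 1000, the fit of the score ladder, the scaling built on it and the second test of neighbouring peaks were chosen after the values were seen. The tests of joined peaks and of distances to the other list and the first test of neighbouring peaks were also chosen after the lists had been examined, but before the values they gave were seen.

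Some scores recur exactly, on a ladder of steps that holds 1512 peaks (3.15%) at 0 Gy and 1353 (3.74%) at 5 Gy within a tolerance of 0.011. In the 0 Gy list the 11 most frequent rungs run from 95.46 to 204.81, and in the 5 Gy list the 11 rungs run from 90.58 to 201.49. The hypothesis that a rung is the Poisson tail of a whole count over 1 background per list was tested by fitting that background. The fit gave 1.644 counts per window at 0 Gy and 1.506 at 5 Gy, and the largest distance of any rung from the fit was 0.0043, below the rounding of the scores. For the peaks on the ladder, this is consistent with a common background 8.4% lower at 5 Gy, at which 11 counts suffice for a p-value of 1e-06, against 12 at 0 Gy. Such a background is the product of depth and window length, and neither is known alone.

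The first pattern is the lower number of peaks at 5 Gy. Loss of peaks near the threshold stays open. Of the 20064 peaks found only at 0 Gy, 83.1% scored under 150. Such scores are common, since 22271 of all 47930 peaks at 0 Gy scored at least 150, and 150 lies well above the threshold of 60. Of the 5866 peaks at 0 Gy with a score of at least 1000, 28 lacked a match. The number of such peaks at 5 Gy, 80.6% of that at 0 Gy, also falls when peaks score lower or merge. Joining of neighbouring peaks into single calls stays open for part of the difference. Joining within 10 kb brought the number at 5 Gy to 90.7% of that at 0 Gy, between the bounds set for and against it. This value cannot decide, because such joining also raises the ratio where extra 0 Gy peaks lie near other peaks. A 0 Gy peak inside a longer 5 Gy call counts as shared. Shared peaks numbered 27866 at 0 Gy and 26431 at 5 Gy, and unmatched peaks 20064 and 9785. Most of the difference thus lay among unmatched peaks, which joining into single calls leaves unexplained. A lower depth at 5 Gy also stays open: scaling all 0 Gy scores by the background ratio of 0.916 left 44358 peaks over the threshold, 22.5% more than the 5 Gy list, but the scaling assumes that scores follow depth in proportion and that the windows were equal. An effect of irradiation on HuR binding or on RNA abundance stays open and was not tested, since dose and library cannot be told apart with 1 library per group.

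The second pattern is the 32 peaks with a score of at least 1000 in one list only, 28 at 0 Gy and 4 at 5 Gy. A left-out stretch of chromosome that reaches 200 kb or more to both sides of such a peak is argued against. None of the 32 lacked a peak of the other list within 200 kb (0.0%, 95% interval 0.0 to 10.7). Shorter left-out stretches were not tested, because they leave peaks of the other list within that distance. Shifted borders of one binding region could explain the 6 peaks (18.8%, 95% interval 8.9 to 35.3) that had a peak of the other list within 1 kb, and the interval leaves open whether that share exceeds the bound of 25% set beforehand. A high IgG signal at the other dose, which would remove a call, and a change of HuR binding were not tested, as the lists hold no IgG values.

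The third pattern is that unmatched peaks lie next to each other. Of neighbouring peaks within 10 kb, both were unmatched in 22.79% of cases at 0 Gy and 9.98% at 5 Gy, against at most 20.32% and 8.89% in 1000 shuffles of the match status within score classes, but neighbours under one long call of the other list are matched together by construction. With such neighbours counted once and the status shuffled within classes of score and length, the values were 25.94% at 0 Gy (highest shuffle 24.43%, mean 23.97%) and 11.26% at 5 Gy (highest shuffle 10.50%, mean 9.88%). Both values lay above every shuffle, but they do not decide against calling noise that is independent from peak to peak. The classes are wide: the shared percentage at 0 Gy was 47.7% at scores from 100 to under 150 and 65.6% from 150 to under 250. Neighbours may have similar scores within a class. The local density of the other list was not held either. Differences of whole transcribed regions between the libraries, in HuR binding, RNA abundance or IgG background, stay open as candidate explanations and were not tested.

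The highest score in both lists, 3233.06, equals −10 log10 of the smallest positive number in double precision (3233.06). The 2481 peaks at 0 Gy and 2000 peaks at 5 Gy tied at 3100 stand against 69 and 55 peaks per 100 score units just below. Tied peaks had a median length of 2370 bp at 5 Gy (95% interval 2275 to 2510) and of 2160 bp at 0 Gy (95% interval 2070 to 2263), and peaks scored from 2900 to under 3100 had medians of 1732 bp (95% interval 1250 to 2435) and 2186 bp (95% interval 1586 to 2677). Peaks above 3100 were 85 at 0 Gy and 70 at 5 Gy, with median lengths of 1261 and 1769 bp, so the highest scores do not mark the longest peaks. Scores thus ran on past 3100 up to the double-precision limit, and 3100 was not a ceiling. A score of 3100 taken at face value does not account for so many exact ties. These values argue against placing the tied peaks below those above 3100. The caller's rule for the tie is not given in the sources used here.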
